A study of Argopecten irradians irradians with 6 samples.

How the data were processed

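MicroRNAs (miRNAs, short RNAs that repress the messenger RNAs they pair with) were measured by small-RNA sequencing of the adductor muscle, the muscle that closes the shell, of the bay scallop Argopecten irradians irradians. The 6 libraries came from the white muscle of Bohai Red scallops (3 libraries) and the orange muscle of QN Orange scallops (3 libraries). Per the labels, 9 muscles were taken from each strain and every 3 of them were pooled into 1 library. A difference between the groups is therefore a difference between strain and colour together, and the spread within a group is the spread between pools.

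A count table and a TPM table, each with 5446 rows, were used as deposited. The count table holds whole-number counts per miRNA name in 6 columns, deposited by the authors with no normalization, and the TPM table holds deposited values scaled to the same total in each column. For the 6 columns that both tables share, each deposited TPM value equalled the count divided by the column total times 1000000, within 5.00e-05, so it carried no length term. The adapter trimming, the aligner, the reference set of miRNAs and the prediction tool were not given in the sources used here, and no genome was used.

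The columns of the tables are named by a letter and a number and do not spell out the samples. Columns with the letter B were read as Bohai Red because that letter begins the strain's name and occurs in no title of the other group. Columns with the letter G were read as QN Orange because they are the other 3 columns of the 6-column count table. The numbers were taken from the column names and the titles. The reading of the letters is an inference that the files did not settle: the split into 3 and 3 libraries and the sizes of the differences do not depend on it, but the direction of every difference does, together with every statement about 1 named strain. The TPM table has 9 more columns of per-sample values under 3 other names, of which 1 could also be read as Bohai Red. They are absent from the count table and were not used.

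Each row of the tables is a miRNA name with the prefix of a species, and the same reads were counted under many names. Of the 5446 rows, 1327 were at 0 in all 6 libraries. The other 4119 rows held 1005 distinct count profiles, and 3486 of them shared their profile with at least 1 other row. There were 4918 rows with a family name, from 134 species prefixes and 188 families, and 528 predicted miRNAs named by a contig and a number. Column totals of 85674751 to 152002629 counts are therefore sums over repeated names and not numbers of reads; the sum over the most abundant row of each family was 2092825 to 4001516. Rows that repeat each other are not independent, so adjusted p-values and gene set tests over rows do not have their nominal meaning. Counts were also summed per family, after removal of the species prefix, arm, letter and copy suffix, with each predicted miRNA kept as its own family. A sum adds the same reads once per name. Family counts therefore overstate the reads, and adjusted p-values over families do not have their nominal meaning either. Families whose sequences are nearly identical, such as let-7 and miR-98 or miR-99 and miR-100, can still share reads, and their values are uncertain to that degree.

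Differences were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by group, glmQLFit with robust = TRUE, and glmQLFTest), with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 differences are orange minus white. The standard error (SE) of a log2 difference was computed as its size divided by the square root of the F statistic. CPM are counts per 1000000 on TMM-scaled library sizes. The filter kept 2006 rows and 156 families, of which 78 were named and 78 predicted. The median log2 difference of the 156 families was 0.32 under TMM, -0.03 under DESeq2 size factors and 0.02 under library totals, so differences relative to the median are given beside the fitted ones where they matter.

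Lists of miRNA families were fixed before the data were examined: 12 lists covering muscle, neural, epithelial and sensory, gut and digestive gland, ciliated cell, immune cell, let-7 complex, K box miR-2 and miR-71, lipid and energy metabolism, pigment cell and eye, lophotrochozoan, and growth and apoptosis miRNAs. They were tested over rows with camera in limma 3.58.1 at a preset correlation of 0.01, for lists with at least 3 tested rows, and also with an estimated correlation, with fry and over family sums. A list's count of calls is given over all families and adjusted over the list alone. Shares of counts were compared with exact two-sided permutation tests of 3 against 3 libraries, for which the smallest possible p is 0.1, so these tests could not pass 0.05.

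The rule for named miRNAs, also fixed before the data were examined, took the 10 higher and 10 lower called rows with the smallest p whose groups did not overlap, further called rows with a family name up to 5 per direction, the 10 most abundant rows, miR-1 and miR-133, and any family of the lists whose sum passed the threshold. No row passed the threshold, so the first parts of the rule named none. Other families named in the text as called, near the threshold or differing between libraries were chosen after their values were seen, and members of the lists are named as examples.

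The alternatives fixed in advance were DESeq2 size factors, library totals and upper-quartile factors in place of TMM, removal of the most abundant miRNA, no filter or a filter of 10 counts in 3 libraries, robust = FALSE, DESeq2 1.42.0, limma on log2(TPM + 1) and log2(TPM + 0.1), a requirement of 2-fold, the replicate number as a block, and leaving out each library. Chosen after seeing the data were leaving out both libraries numbered 1, merging identical rows, TMM factors from family sums, and 1 row per family. Scaling to the sum of all families other than miR-1 and miR-133, also with 1 row per family, was also chosen after seeing the data and served only to test an explanation. The calculations were tested on simulated counts. Of the simulated rows, 1957 passed the filter and 200 were changed. The test recovered 0% at 2-fold, 17.9% at 4-fold and 59.1% at 8-fold with 0 false calls. Of the simulated families, 141 passed the filter and 30 had been changed, of which 9, 8 and 10 were tested at those folds. It recovered 0%, 0% and 10% of them, again with 0 false calls, so a family that was not called can still differ several-fold. The simulated spread followed the trend over families, and recovery of a real family can differ: miR-100 and let-7 were called below 2-fold. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.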

Results

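Small RNAs were sequenced from the adductor muscle of 2 strains of bay scallop, the white-muscled Bohai Red and the orange-muscled QN Orange, with 3 libraries per strain and 3 muscles pooled in each library. The series concerns carotenoid accumulation in the orange muscle, and the comparison addresses which miRNAs differ in abundance between orange and white muscle. The count totals were 152002629, 135382374 and 124897706 in white replicates 1 to 3, and 145531327, 85674751 and 136634762 in orange replicates 1 to 3. These totals count the same reads under many species' names, and the sum over 1 row per family was 2092825 to 4001516 per library. The library columns are identified by letters only, and the column set B was read as Bohai Red and the set G as QN Orange. Every "higher" and "lower" given here rests on that reading, while the sizes of the differences do not.

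Summed over all species names, most of the counts in both muscles belonged to 4 families. These were miR-133 and miR-1, which are conserved muscle miRNAs, and miR-100 and let-7, which are encoded together in many animals and of which let-7 controls developmental timing. Together they held 94.3% to 96.9% of the counts of a library, a share that grows with the number of names a family has. With 1 row per family they held 60.7% to 66.3%, and the predicted miRNA Contig117_4460, which has 1 name, held 26.9% ± 2.26 in orange and 22.9% ± 0.0697 in white muscle (exact permutation p = 0.1). In orange muscle miR-100 held 36.0% ± 3.35 of the counts (SD, n = 3 libraries), against 22.2% ± 0.0213 in white muscle. The share of miR-1 was 12.9% ± 1.82 in orange and 20.5% ± 1.33 in white muscle. The share of miR-133 was 41.3% ± 3.59 in orange and 49.2% ± 2.23 in white muscle. The groups did not overlap for these 3 families, and each gave p = 0.1 in an exact two-sided permutation test, the smallest p that 3 against 3 libraries allow (adjusted p = 0.143 over 10 shares). For let-7 the share was 5.63% ± 1.36 in orange and 3.82% ± 0.422 in white muscle, where the ranges overlapped (exact permutation p = 0.2, adjusted 0.2). With 1 row per family, the shares in orange and white muscle were 21.1% ± 0.936 and 13.5% ± 0.300 for miR-100, and 11.9% ± 2.27 and 18.7% ± 0.835 for miR-1 (exact permutation p = 0.1 each). They were 22.5% ± 3.09 and 26.8% ± 1.84 for miR-133, and 7.70% ± 1.52 and 5.30% ± 0.652 for let-7, and the ranges of these 2 overlapped (exact permutation p = 0.2 each).

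Ratios within a library need no scaling between libraries. The log2 ratio of miR-100 to miR-133 was -0.20 ± 0.26 in orange and -1.14 ± 0.07 in white muscle (SD, n = 3 each), a difference of 0.94. The ratio of miR-100 to miR-1 differed by 1.36, and that of let-7 to miR-133 by 0.79. The ratio of miR-1 to miR-133 was -1.68 ± 0.09 in orange and -1.26 ± 0.16 in white muscle, a difference of -0.42. For these 4 ratios the groups did not overlap, and the exact two-sided permutation p was 0.1 for each, before and after adjustment over the 4.

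Between the groups, 14 of 156 families passed the threshold on family sums, 8 higher and 6 lower in orange muscle. The sums repeat reads over names, and with 1 row per family 13 of these 14 passed. The abundant family miR-100 rose 1.95-fold, from 203121 ± 15360 to 395551 ± 45401 CPM (SD, n = 3), with a log2 difference of 0.96 (SE 0.127, adjusted p = 0.0258, edgeR). let-7 rose 1.75-fold, with a log2 difference of 0.80 (SE 0.146, adjusted p = 0.0292). Relative to the median family, which itself lay at 0.32, these differences were 0.64 and 0.48. Of the families with fewer counts, miR-281 rose 13.8-fold, from 40.3 ± 21.8 to 554 ± 340 CPM, with a log2 difference of 3.78 (SE 0.707, adjusted p = 0.0292), and miR-46 rose by the same log2 difference of 3.78 (SE 0.733, adjusted p = 0.0292). The fold of miR-281 was 6.75 without orange replicate 3 and 8.96 without white replicate 1, and that of miR-46 was 6.67 and 8.98. Neither passed in any of the 6 fits that left out 1 library, and each passed in 10 of the 19 other settings. The 2 families may hold the same reads, so they are not 2 independent calls. The family miR-4758 also passed, at 2 to 4 counts per white library and 10 to 21 counts per orange library. Falls were found for miR-1985 and miR-1993, which are known from molluscs and annelids. miR-1985 fell 2.28-fold, from 491 ± 53.3 to 215 ± 27.2 CPM (SE of the log2 difference 0.233, adjusted p = 0.0292), and miR-1993 fell 6.64-fold, from 13.4 ± 2.36 to 2.02 ± 0.765 CPM (SE 0.469, adjusted p = 0.0292). The other 7 were predicted miRNAs known only by contig. Contig118_4651 rose 4.69-fold, from 39.8 ± 5.35 to 187 ± 40.0 CPM (SE 0.309, adjusted p = 0.0258), and Contig632_21629 fell 3.43-fold, from 280 ± 63.7 to 81.7 ± 10.8 CPM (SE 0.299, adjusted p = 0.0292). In 4 of these 7, the lower group held at most 2 counts in all, and no fold is given for them. Of the 14 called families, 10 lay outside the rule for named miRNAs and were named or counted after their values were seen.

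**Figure D1:**
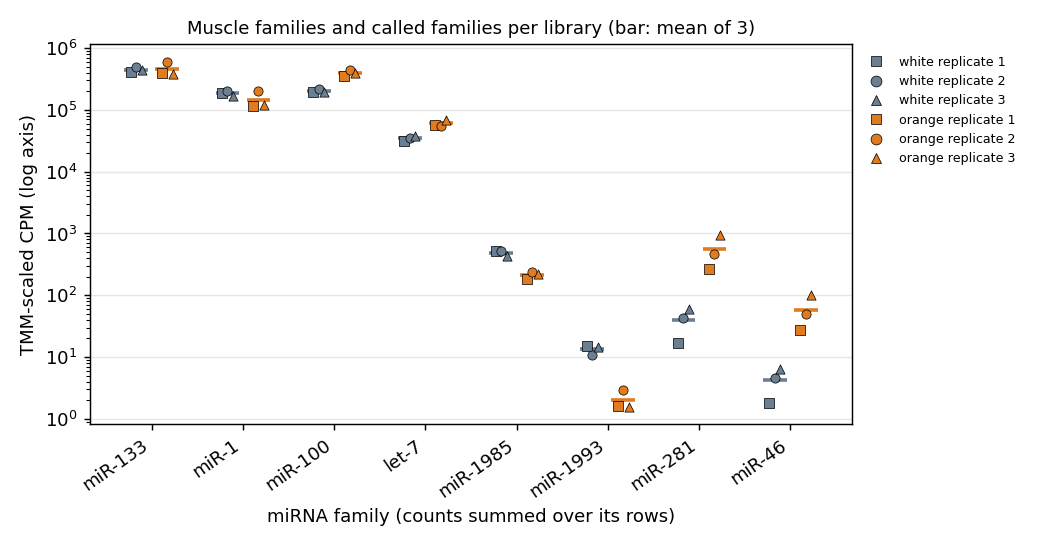
Each point is the TMM-scaled CPM of 1 family in 1 library on a log axis, with squares, circles and triangles for replicates 1, 2 and 3, white muscle in grey, orange muscle in orange, and a bar at the mean of 3 libraries. The 3 orange libraries lie above the 3 white ones for miR-100, let-7, miR-281 and miR-46 and below them for miR-1985 and miR-1993, while the libraries overlap for miR-133 and miR-1.

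All 14 families kept the sign of their difference in every one of the 19 other settings in which they could be tested. The groups did not overlap in any of the 14, and the settings refit the same libraries, so the kept sign was largely set by the selection. The number of calls did not hold in the same way: it was 1 without white replicate 1, 0 without white replicate 2, 0 without white replicate 3, 2 without orange replicate 1, 0 without orange replicate 2 and 0 without orange replicate 3. It was also 0 with upper-quartile factors, and the split of higher to lower calls went from 8 to 6 under TMM to 3 to 6 under DESeq2 size factors and 6 to 8 under library totals. The groups did not overlap in 52 of the 156 families, or 33.3%, where chance gives 10%, and in 280 of the 2006 single rows, a share much nearer to chance. The rows had their own TMM factors, 1.94, 0.663 and 0.685 in white replicates 1 to 3, against 1.15, 1.01 and 1.15 for families. With TMM factors from family sums, 530 rows had an unadjusted p under 0.05 by edgeR, against 172 with their own factors. Rows also repeat the same reads, so the shares of families and rows cannot be compared directly.

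**Figure D2:**
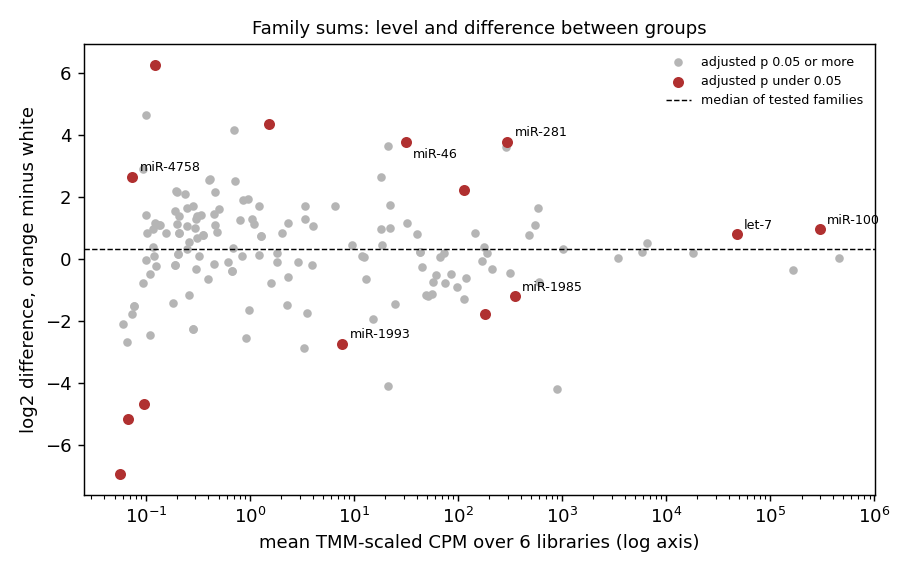
Each point is 1 of the 156 families, with its mean TMM-scaled CPM over 6 libraries on a log axis and its log2 difference, orange minus white, on the vertical axis. The 14 families past the threshold are red, and the dashed line marks the median of 0.32; let-7 and miR-100 are the called families of high abundance, and a group of called predicted miRNAs lies at the lowest counts.

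The muscle list had 3 tested families, and none passed the threshold. The log2 difference of miR-1 was -0.36 (SE 0.245, adjusted p = 0.379, edgeR), or -0.68 relative to the median family. It stayed negative in all 19 other settings, from -0.78 to -0.36, and passed the threshold in 3 of them. miR-133 had a log2 difference of 0.04 (SE 0.208, adjusted p = 0.903), and its sign turned in 15 of 18 settings, among them DESeq2 size factors (-0.38) and library totals (-0.25). The third member, miR-206, was at 1.28 ± 0.649 CPM in orange and 1.16 ± 0.394 CPM in white muscle.

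In the let-7 complex, all 5 tested families had a log2 difference above 0, and also above the median of all families, 0.32. Since let-7 and miR-98, and miR-99 and miR-100, can share reads, these are not 5 independent families. Over all families, 2 passed (miR-100 and let-7), and 4 passed when adjusted over the list alone, with miR-98 and miR-99 added. The values of those 2 were 0.99 (SE 0.310, adjusted p = 0.136 over all families, edgeR) for miR-98 and 1.65 (SE 0.548, adjusted p = 0.142) for miR-99. miR-125 had a log2 difference of 1.09 (SE 0.543, adjusted p = 0.285). In orange replicate 1 the level of miR-99 was 3.23-fold that of the other 2 orange libraries, and without both libraries numbered 1 its log2 difference was 0.68. Without both libraries numbered 1, let-7 had a log2 difference of 0.53 and no longer passed (adjusted p = 0.159), while miR-100 passed at 0.78 (adjusted p = 0.0347). let-7 also lost its call without each of the 6 libraries in turn (log2 difference 0.29 to 0.78), and miR-100 without each but 1 (0.56 to 0.98). Over the 19 other settings, let-7 passed in 2 and miR-100 in 10. Among those in which let-7 did not pass were DESeq2 size factors (log2 difference 0.39, adjusted p = 0.407), library totals (0.56, 0.191), removal of the most abundant miRNA (0.72, 0.171) and 1 row per family (0.71, 0.123). miR-100 did not pass with DESeq2 size factors (0.56, adjusted p = 0.198, edgeR), upper-quartile factors (0.51, 0.482) or no filter (0.83, 0.0528). By the DESeq2 test it did not pass either (0.56, adjusted p = 0.214).

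In the lophotrochozoan list, 2 of 7 tested families fell (miR-1985 and miR-1993), both over all families and adjusted over the list alone. Their log2 differences were -1.19 and -2.73, and 5 of the 7 families lay below 0. miR-1990 and miR-1994 had log2 differences of -4.10 (SE 1.79, adjusted p = 0.230) and -2.88 (SE 1.56, adjusted p = 0.342), but both rested on white replicate 1. miR-1990 was 53.5-fold higher there than in the other 2 white libraries, and miR-1994 was at 16.5 CPM there against 0.425 and 0.601 CPM. Without both libraries numbered 1, their log2 differences turned to 0.21 and 0.70, and 4 of the 7 families lay below 0. In that setting miR-1985 and miR-1993 passed at -1.29 and -2.75 (adjusted p = 0.0284 and 0.0347). Without each of the 6 libraries in turn, neither passed in any of the 6 fits, at log2 differences of -1.59 to -1.19 for miR-1985 and -3.15 to -2.82 for miR-1993.

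The lists for other tissues gave no family past the threshold over all families. Of the 6 neural families, miR-124, which is abundant in neurons, had a log2 difference of 3.61 (SE 1.69, adjusted p = 0.251), and it was 54.2-fold higher in orange replicate 1 than in the other 2 orange libraries. miR-9 was 9.04-fold higher in orange replicate 1 and 6.09-fold higher in white replicate 1 than in the others of their groups. Of the 5 epithelial and sensory families, miR-8 had a log2 difference of 0.40 (SE 1.01) and miR-183 one of -1.15 (SE 1.14). In white replicate 1, miR-8 was 6.54-fold, miR-263 7.88-fold, miR-183 14.2-fold and miR-96 5.22-fold higher than in the other 2 white libraries, and in orange replicate 1 the folds of miR-8, miR-263, miR-183 and miR-96 were 4.28, 2.38, 1.79 and 1.51. The fifth, miR-141, was under 1 CPM and went the other way in white replicate 1, with 0 counts against 24 and 120 in white replicates 2 and 3; it had 120 counts in orange replicate 1 and 0 in the other 2 orange libraries. Without both libraries numbered 1, the log2 difference of miR-124 turned to -0.78 and that of miR-183 to 0.71. The gut and digestive gland list had 4 of 5 families above 0, among them miR-375 at 2.65 (SE 0.831, adjusted p = 0.136) and miR-194 at 1.72 (SE 0.550, adjusted p = 0.136). miR-34, of ciliated cells, had a log2 difference of 0.84 (SE 0.274, adjusted p = 0.136) and passed only when adjusted over the list alone, in which it was the 1 family tested. Without both libraries numbered 1, miR-219 of the neural list and miR-122 of the gut and metabolism lists passed (adjusted p = 0.0271 and 0.0441, edgeR). They had 156 and 497 counts in the remaining orange libraries and 0 in the remaining white ones. These counts were summed over 80 and 61 names, so few reads may lie behind them and the p-values lack their nominal meaning. In this fit, 459 of the miR-122 counts lay in orange replicate 3 and 38 in orange replicate 2. White replicate 1, left out there, held 780 counts of miR-219 and 38 of miR-122, and over all libraries the log2 difference of miR-219 was -1.66 (SE 2.86, adjusted p = 0.729) and that of miR-122 was 4.16 (SE 2.74, adjusted p = 0.364). The immune list also had 1 tested family, miR-21, at 0.489 ± 0.344 CPM in orange and 0.185 ± 0.182 CPM in white muscle.

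**Figure D3:**
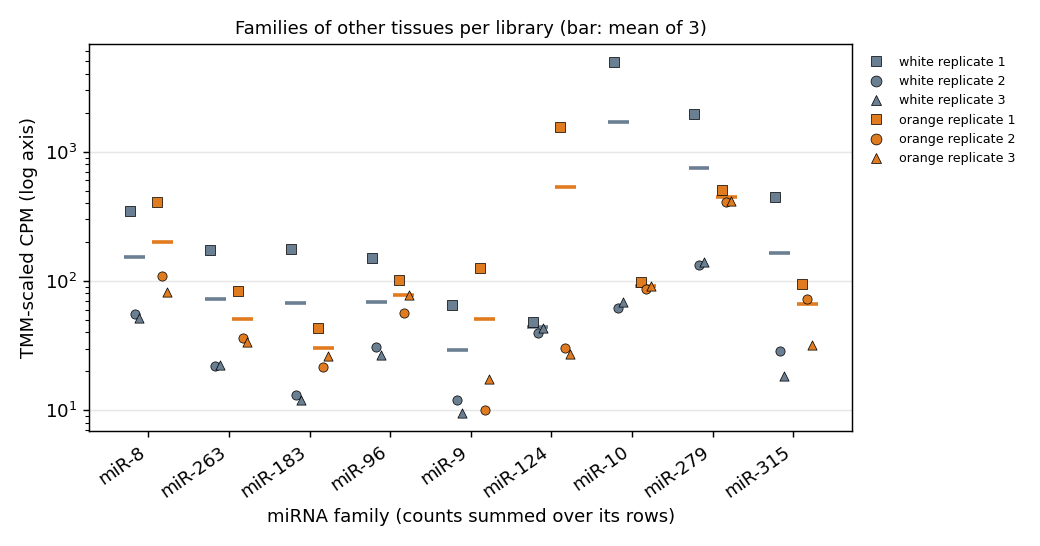
Each point is the TMM-scaled CPM of 1 family in 1 library on a log axis, with squares for replicates 1, circles for replicates 2, triangles for replicates 3 and a bar at the mean of 3 libraries. White replicate 1 lies above the other white libraries for all families shown, by only 1.165-fold of their mean for miR-124. Orange replicate 1 lies above the other orange libraries for all families shown, most for miR-124, miR-9 and miR-8 and by only 1.11-fold for miR-10.

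The remaining lists had no family past the threshold, over all families or adjusted over the list alone. In the lipid and energy metabolism list, miR-33, which in vertebrates lies within genes that regulate sterol synthesis, had a log2 difference of 0.96 (SE 0.373, adjusted p = 0.212), and miR-278 one of -1.93 (SE 1.56, adjusted p = 0.452). miR-278 was at 70.0 CPM in white replicate 1 and at 1.33 and 1.72 CPM in the other 2 white libraries, and without both libraries numbered 1 its log2 difference turned to 1.98 (adjusted p = 0.0772). Of the pigment cell and eye list, miR-184 was at 19252 ± 4464 CPM in orange and 16651 ± 5034 CPM in white muscle, a log2 difference of 0.21 (SE 0.279). In the K box list, miR-71 and miR-2 had log2 differences of 0.21 (SE 0.172) and 0.04 (SE 0.203). In the growth and apoptosis list, bantam had a log2 difference of -0.92 (SE 0.413, adjusted p = 0.230) and miR-92 one of 0.77 (SE 0.437, adjusted p = 0.363).

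Tested over rows with camera at the preset correlation of 0.01, 11 of 11 lists passed the threshold. With an estimated correlation none did, at adjusted p = 0.1004 for the lophotrochozoan list and up to 0.775 for the others. Over family sums 0 of 8 lists passed (lowest adjusted p = 0.119), and by fry 1 of 11 passed, the lophotrochozoan list (adjusted p = 0.00551). Row and family medians differed in sign for 3 lists. The neural list was ranked downward by camera although the median of its rows was 0.92. Without orange replicate 2, 6 lists passed at the preset correlation. The rows of a list repeat the same reads, which the preset correlation does not take into account.

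Among single rows, 0 of 2006 were higher and 0 were lower in orange muscle by edgeR (lowest adjusted p = 0.0744). At an unadjusted p under 0.05 there were 65 higher and 107 lower rows, and DESeq2 called 47 higher and 18 lower. The count was 0 without white replicate 1 and 0 without orange replicate 3, but 76 without white replicate 2, 203 without white replicate 3, 143 without orange replicate 1 and 188 without orange replicate 2. The TMM factors over rows were 1.94 in white replicate 1, against 0.663 and 0.685 in white replicates 2 and 3 and 0.918 to 1.12 in the orange libraries.

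The 10 most abundant rows were the predicted Contig117_4460 and 9 rows of miR-133 under different species' names. Contig117_4460 had a TPM of 6944 ± 925 in orange and 5864 ± 155 in white muscle (SD, n = 3). In the TMM-scaled fit of families it was at 7619 ± 970 CPM in orange and 5350 ± 333 CPM in white muscle. The log2 difference of 0.51 (SE 0.166, adjusted p = 0.136, edgeR) belongs to that fit. The row dpe-miR-133 had a TPM of 5765 ± 497 in orange and 6866 ± 320 in white muscle. These 10 rows held 5.86% ± 0.361 of the counts in orange and 6.75% ± 0.270 in white muscle, a difference of -0.882 percentage points (exact two-sided permutation p = 0.1). With 1 row per family, the 10 most abundant held 94.4% ± 1.11 and 93.1% ± 1.78, a difference of 1.22 in the other direction (exact permutation p = 0.4). Predicted miRNAs held 0.759% ± 0.101 of the counts in orange and 0.670% ± 0.00930 in white muscle (exact permutation p = 0.2). Without Contig117_4460 the difference was -0.0193 percentage points, while with 1 row per family predicted miRNAs held 29.4% ± 2.46 and 26.1% ± 0.269, a difference of 3.23 percentage points (exact permutation p = 0.1 for each).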

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

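Leaving out both libraries numbered 1, merging identical rows, TMM factors from family sums and 1 row per family were chosen after the data were seen. The calls of single rows depended on the setting. Against 0 higher and 0 lower rows by edgeR with TMM, library totals gave 74 and 56, no filter 1 and 4, DESeq2 47 and 18, limma on log2(TPM + 1) 97 and 56, limma on log2(TPM + 0.1) 99 and 60, TMM factors from family sums 128 and 10, and merged rows with those factors 53 and 9. Merged rows alone gave 4 lower rows, and leaving out both libraries numbered 1 gave 1 lower row. Leaving out 1 library gave 0 to 122 higher and 0 to 92 lower rows. Against 14 called families, DESeq2 size factors gave 9, upper-quartile factors 0, no filter 5, DESeq2 22 (11 of them shared), and leaving out 1 library 0 to 2; leaving out both libraries numbered 1 gave 18 (8 shared) and 1 row per family 13 (13 shared). No filter tested more families (491). Leaving out a library tested fewer samples, but leaving out both libraries numbered 1 tested fewer still and kept 8 of the 14 calls. The rest of its 18 calls are weaker ground, since miR-122, miR-126, miR-143 and miR-219 among them had 0 counts in 1 group. By the 8 calls kept, the number of samples alone does not account for the fall to 0 to 2. The cause was not tested for any setting. Of 11 lists, 0 passed with an estimated correlation, 1 by fry, 0 over family sums, and 6 to 11 when 1 library was left out.

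The titles give both groups the numbers 1 to 3. With the replicate number as a block, 27 rows were higher and 7 lower, and 4 families were called. Deviations of same-numbered libraries correlated at -0.164, -0.0324 and 0.0148, which gave no sign of pairing. Such values cannot exclude a pairing or a shared batch. miR-8, miR-263, miR-183 and miR-96 were raised in both libraries numbered 1. A strong rise of miR-10 was seen in white replicate 1 alone and one of miR-124 in orange replicate 1 alone.

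The share of the 10 most abundant rows differed by -0.882 percentage points, and by 1.22 with 1 row per family. The share of predicted miRNAs differed by 0.0887 percentage points, by -0.0193 without the most abundant miRNA and by 3.23 with 1 row per family. For the named families, 258 values under other settings comprised 139 on the same side of the threshold and in the same direction, 101 that lost the threshold, 3 that gained it and 15 that turned direction. These 15 were all of miR-133, whose log2 difference was 0.04 and became -0.38 with DESeq2 size factors, -0.25 with library totals, -0.42 with upper-quartile factors, -0.10 with no filter, -0.0031 with 10 counts in 3 libraries, -0.38 by DESeq2, -0.25 by limma with either pseudocount, -0.0466 with 1 row per family, -0.18 without both libraries numbered 1, and -0.29 without white replicate 1, -0.12 without white replicate 3, -0.11 without orange replicate 1, -0.30 without orange replicate 2 and -0.23 without orange replicate 3; it was 0.0680 without white replicate 2. The cause was not tested. Depth did not limit the abundant families, but 4 predicted calls rest on at most 2 counts in 1 of the groups.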

Other observations

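The families in this paragraph lie outside the lists and were chosen after their values were seen. Nearest to the threshold without passing it were miR-2478, with a log2 difference of 2.09 (SE 0.518, adjusted p = 0.0668, edgeR) at under 1 CPM, miR-1175, and a predicted miRNA (adjusted p = 0.0734). miR-1175 was at 35.6 ± 4.81 CPM in orange and 76.9 ± 9.49 CPM in white muscle (SD, n = 3), a log2 difference of -1.11 (SE 0.278, adjusted p = 0.0668, edgeR). Farther from it, miR-190 had a log2 difference of -1.19 (SE 0.482, adjusted p = 0.214) and miR-750 one of 1.17 (SE 0.463, adjusted p = 0.214). miR-10, which is encoded within the Hox clusters of many animals, was at 92.0 ± 5.98 CPM in orange muscle and was 76.4-fold higher in white replicate 1 than in the other 2 white libraries. In the same library miR-279 was 14.2-fold and miR-315 18.8-fold higher than in the other 2. The log2 difference of miR-279 between the groups was -0.75 (SE 1.09, adjusted p = 0.676) and became 1.34 (SE 0.215, adjusted p = 0.0284) without both libraries numbered 1, and miR-1175 passed the threshold there at -1.29 (SE 0.260, adjusted p = 0.0392).

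All tests in this part were chosen after the results they bear on had been seen, except the count of lists over other splits. White replicate 1 and orange replicate 1 each stood apart from the other libraries of their group, with 17 and 5 of 79 families over 4-fold higher than in the others. A candidate explanation is RNA of another tissue in the pooled muscle. The 5 tested epithelial and sensory families had a median log2 difference from the other libraries of the group of 2.71 in white replicate 1 and 1.25 in orange replicate 1, and miR-8, miR-263, miR-183 and miR-96 lay above them in both. The fifth, miR-141, had 0 counts in white replicate 1 against 24 and 120 in the other white libraries, too few to count for or against. miR-1 and miR-133 differed by 0.05 and -0.21 in white replicate 1 and by -0.46 and -0.32 in orange replicate 1. They hold much of the counts of every library, which leaves little room for both to rise several-fold, so their steadiness is weak evidence. Library size would move all families alike and was argued against in white replicate 1, where the epithelial and sensory median lay 2.79 above the muscle median. Which tissue it would be stays open, since miR-10 rose strongly in white replicate 1 alone and miR-124 in orange replicate 1 alone. A difference between the pooled animals was not tested.

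The second pattern is the 14 called families. A candidate explanation is RNA of another tissue in the libraries numbered 1. Without both of them the called families kept a median of 96.2% of their log2 difference, so most of these differences did not rest on those libraries. The calls were selected with them included, however, and a family raised in 1 library alone has a spread too wide to pass. The share kept was thus largely set by the selection and cannot decide on the explanation. Of the 14, 6 lost their call with fewer libraries, let-7 (66.4% kept) and 5 families with few counts in 1 group. A lower share of muscle miRNAs in the orange counts would raise every other family alike. Against this as the whole cause, the other families did not move alike: with 1 row per family and libraries scaled to all non-muscle families, 7 of 140 were higher and 11 lower past the threshold. In family sums scaled to all non-muscle families, miR-281, miR-46 and 2 predicted miRNAs stayed past it (4 of 4, adjusted p = 0.0265 to 0.0426, edgeR). Since miR-281 and miR-46 may hold the same reads, these are not 4 independent families. Calls in both directions were already present under TMM, and rescaling shifted most called families by similar amounts. The counts after rescaling therefore largely repeat those calls. In family sums, miR-100 alone held 76.1% of the non-muscle total, so that test is largely a comparison with miR-100. Summed over all names, miR-100 and let-7 were at 0.10 and -0.0488 when scaled to all non-muscle families, of whose counts they hold 88.6% themselves. They were therefore tested with 1 row per family (39.3%). Contig117_4460 is another large part of that total, at 22.9% of all 1-row counts in white and 26.9% in orange muscle. The test with 1 row per family is thus in part a comparison with this predicted miRNA. There miR-100 stayed higher at 0.38 (SE 0.0622, adjusted p = 0.0166, from 0.84 with TMM), which argues against the muscle share as its whole cause, while let-7 was at 0.26 (SE 0.137, adjusted p = 0.231). The explanation stays open for let-7 and for the 2 higher families with few counts, of which 1 stayed past the threshold (adjusted p = 0.0273) and miR-4758 did not (0.0718); strain, muscle colour and anything else that differed between the groups also stay open, untested.

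The third pattern is the equal rise of miR-281 and miR-46. The sum of miR-46 was 10.3% to 10.7% of that of miR-281 in the 6 libraries, with a coefficient of variation of 1.60%, while each sum varied 42.0-fold. miR-46 had 3 rows and miR-281 had 28, so the steady ratio could follow from the same reads being counted under both names. The pair may be 1 miRNA and not 2, and it cannot stand for 2 independent calls. The sequences were not compared. No biological explanation was tested for it.

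The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For families the real split gave 14 calls and the highest other split 1, so 1 of the 10 splits gave as many. For lists the real split gave 11 and the highest other 9, and 1 of the 10 gave as many. For rows the real split gave 0, which any split equals or exceeds, and the highest other gave 181. Of the 4 splits that put white replicate 1 and orange replicate 1 together, 2 gave 181 and 153 rows and 2 gave 0, and the 6 splits that part them gave 0. The splits with 181 and 153 rows called 0 families. They had 10 and 6 families at an unadjusted p under 0.05 by edgeR, against 36 in the real split. Since rows repeat the same reads over many names, these row counts cannot by themselves show a structure of the samples, which was not tested further.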
